A study of Homo sapiens with 12 samples.

How the data were processed

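RNA-seq libraries were made from total RNA of the human mantle cell lymphoma line Mino, left untreated or exposed for 4 h to OTX015, ARV-825 or ARV-771 at 500 nM. Each of the 4 groups held 3 biological replicates, 12 libraries in all. Per the submitters' processing notes, the authors aligned reads with TopHat2 2.0 and estimated FPKM with Cufflinks 2.0 on the hg19 assembly. The deposited table lists FPKM for coding genes under symbols with versioned Ensembl identifiers. Its header does not name the unit, which was taken from the notes. Quantile normalization across libraries was read from the name of the table and from its values: 99.06% of values above 1 recur in another library. Read depth is not given in the sources used here, so the precision that depth alone would allow cannot be stated. Totals of the values are fixed largely by the quantile step and say nothing about the amount of RNA per cell.

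The table held 18655 gene entries. The 19 duplicates for the pseudoautosomal regions were left out, leaving 18636 genes, and 27 symbols that a spreadsheet had turned into dates were identified by their Ensembl identifier. All per-sample columns were used. A gene was tested when its mean over the 12 libraries was at least 1, which kept 9830 genes. Tests ran on log2(value + 1), with limma 3.58.1 in R 4.3.3: a linear model with the 4 groups (8 residual degrees of freedom), moderated variances with an intensity trend, 2-sided tests, and Benjamini-Hochberg adjustment within each comparison at 0.05. The 6 comparisons were each compound against control and each pair of compounds. Changes are given on this log2 scale, and the added 1 understates the fold of genes at low levels. Levels are means ± SD of FPKM with n = 3 per group. Intervals are 95% confidence intervals. An exact 0 in such tables can be a failed estimate and is described as listed at 0. Coordinates are not given, because the authors' assembly differs from the GRCh38 annotation at hand. That annotation was used only for transcript length, GC content, exon number, sequence motifs and neighbouring genes.

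The choice of genes to name was written before the data were examined, together with the comparisons, tests, gene lists and most alternatives. A set of 21 genes was fixed to be given always: BRD2, BRD3, HEXIM1, SERPINI1, MYC, CCND1, CDK4, CDK6, CDKN1A, BCL2, BCL2L1, MCL1, BCL2L11, BTK, IKZF1, IKZF3, IRF4, PAX5, CRBN, VHL and one gene that, like some list members and the list of BET genes, is not reported here. Added to these are the 10 genes with the greatest change in each direction against control and the 5 in each direction between compounds, among genes past the threshold with a higher group mean of at least 5 and no overlap between the groups' libraries. Each of the 29 lists adds the members past the threshold with the greatest change, or the greatest change of any member if none passes. The lists cover BET genes, the P-TEFb and 7SK complex, blood markers of BET inhibition, ribosome biogenesis, nucleotide and polyamine synthesis, ribosomal proteins, G1/S regulators, CDK inhibitors, G2/M and mitosis, homologous recombination and checkpoint, anti-apoptotic and pro-apoptotic genes, B-cell receptor signalling, B-lineage transcription factors, NF-kB targets, immediate early genes, interferon response, p53 targets, ATF4 and amino acid response, heat shock, hypoxia, cholesterol synthesis and uptake, histones, cereblon ligase, VHL ligase, proteasome, and markers of T cells, myeloid cells and epithelial or stromal cells. Lists with at least 3 tested genes were tested with camera against all other genes (preset correlation 0.01, and again with a correlation estimated from the data) and with fry, which asks whether a set moves on balance in one direction. Member counts are given both at the adjustment over all genes and adjusted over the list alone where the counts differ.

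The controls enter all 3 comparisons with control, which makes unrelated responses correlate. The size of this effect was simulated with 100 draws in which no gene changed, with one spread per gene and, added after the data had been seen, with the spread of each group. The whole procedure was also tested on simulated data with known changes. Alternatives tried were a pseudocount of 0.1, no filter on low values, a mean of at least 5, a replicate block, a fit with only the groups compared (4 residual degrees of freedom), no variance trend, a robust variance prior, weights per library, centring on ribosomal protein genes or on the median of all genes, and leaving out each library in turn. A fit without the ARV-771 libraries and a correction for transcript length and GC content were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Reads shared between paralogs cannot be separated in gene-level FPKM, which makes values of histone genes, of HSPA1A and HSPA1B, and of CCL4 uncertain. Isoforms, protein levels and cell numbers were not analysed here.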

Results

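Mino cells come from a mantle cell lymphoma, a B-cell malignancy in which a translocation drives cyclin D1. BET proteins read acetylated histones and help RNA polymerase II to elongate. OTX015 occupies their bromodomains, whereas the degraders ARV-825 and ARV-771 bring them to the cereblon and VHL ubiquitin ligases. Each compound was given at 500 nM for 4 h, with 3 replicates per group.

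The groups separated cleanly. Correlations between libraries of a group were 0.990 to 0.994 in control, 0.991 to 0.994 in OTX015 and 0.993 to 0.995 in ARV-825, but 0.951 to 0.982 in ARV-771. OTX015 and ARV-825 libraries correlated with each other at 0.981 to 0.990, and control and ARV-771 libraries at 0.896 to 0.915. ARV-771 replicates spread more widely (root mean square SD 0.343 in log2, against 0.167 in control). In ARV-771 replicate 3 the mitochondrially encoded genes made up 23.5% of the summed values and 3112 genes were listed at 0, MT-CO3 and MT-ATP6 among them. The other ARV-771 replicates had mitochondrial shares of 9.77% and 11%, and the other 11 libraries had 4901 to 5467 genes at 0. Transcript length and GC content accounted for 21.9% of the variation of ARV-771 replicate 1 around the gene means, against 0.564% to 6.66% in the other libraries.

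**Figure D1:**
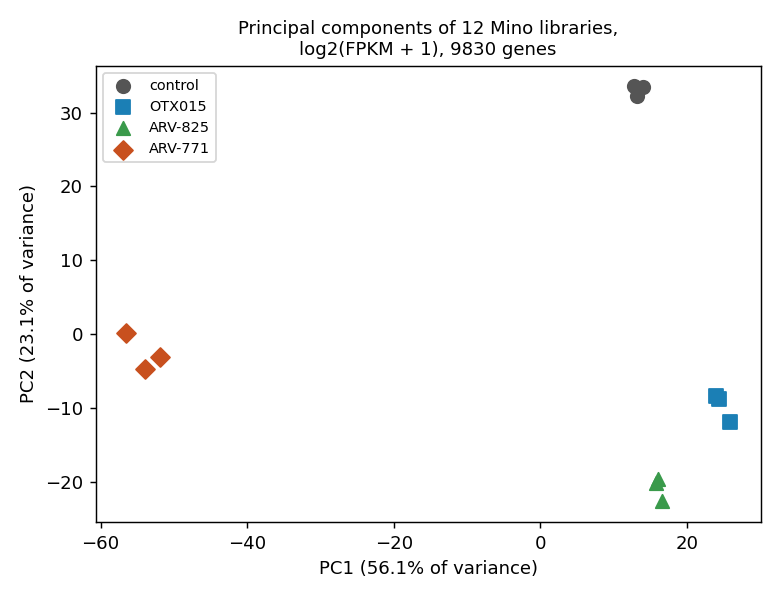
Principal components of log2(FPKM + 1) over 9830 genes, each point a library. The first component (56.1% of variance) parts the ARV-771 libraries (-56.5 to -51.9) from all others (12.7 to 25.9), and the second (23.1%) parts control from OTX015 and ARV-825.

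OTX015 lowered MYC (ENSG00000136997.15), the growth regulator of many B-cell lymphomas, from 235.6 ± 11.4 to 33.5 ± 0.776 (n = 3 each), a log2 change of -2.78 (SE 0.08, adjusted p = 1.81e-09). HEXIM1 (ENSG00000186834.3), which holds the elongation kinase P-TEFb inactive, rose from 6.28 ± 0.135 to 32.3 ± 1.15 (2.19, SE 0.08, adjusted p = 1.05e-08). BRD2 rose from 113.7 ± 9.53 to 244.8 ± 16.8 (1.10, SE 0.21, adjusted p = 0.00139). The survival genes moved apart: MCL1 rose from 31.6 ± 2.05 to 70.1 ± 2.51 (1.13, adjusted p = 2.19e-06) and BCL2L1 fell from 14.8 ± 0.425 to 6.56 ± 0.835 (-1.07, adjusted p = 0.000133). CCND1, the driver of the disease, stood at 315.9 ± 18.8 in control and 293.2 ± 12.2 with OTX015 (-0.11, adjusted p = 0.540).

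The cell-cycle brake CDKN1A rose from 24.0 ± 2.11 to 39.5 ± 0.0501 (0.70, adjusted p = 0.000235). Lymphoid regulators fell: IKZF3 from 31.6 ± 1.96 to 11.9 ± 0.486 (-1.34, adjusted p = 5.23e-05), PAX5 from 18.1 ± 1.5 to 9.27 ± 0.722 (-0.89, adjusted p = 2.2e-05), IKZF1 (-0.80, adjusted p = 7.47e-06) and the kinase BTK (-0.47, adjusted p = 0.000506). IRF4 rose by 0.41 (adjusted p = 0.00998). CDK4 (-0.54, adjusted p = 0.0677), BCL2 (-0.40, adjusted p = 0.179) and CRBN (-0.35, adjusted p = 0.0541) did not pass. VHL rose by 0.27 (adjusted p = 0.0231), a call lost without any one of the control or OTX015 libraries (0.26 to 0.29) or when centred on ribosomal proteins (0.25). BRD3 rose by 0.35 (adjusted p = 0.0452), and this call was lost without any ARV-825 library (0.35), without control replicates 2 (0.30) or 3 (0.31), and without OTX015 replicates 1 (0.37) or 2 (0.26). It was lost too with no filter, a replicate block or centring on ribosomal proteins (0.32). SERPINI1, a blood marker of BET inhibition, was too low to test (0.376 in control, 1.19 with OTX015), as was CDK6 (0.00520 in control), and BCL2L11 was listed at 0 in every group.

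The steepest falls included the adaptor SLA (28.8 ± 0.506 to 3.09 ± 0.232, -2.87), the cytokine IL16 (45.0 ± 1.76 to 8.57 ± 0.621, -2.27), IKZF2 (-2.21), the Toll-like receptor homologue CD180 (-2.18), the proton channel HVCN1 (-2.16) and the plasma-cell receptor TNFRSF17 (-2.11). LRRC14B fell from 25.3 ± 2.93 to 1.57 ± 0.273 (-3.35), and the MYC target TFAP4 (-2.26) and PLD6 (-2.25) fell with it. On the other side stood BZRAP1 (2.14 ± 0.321 to 24.4 ± 0.802, 3.02, adjusted p = 3.15e-07), FAM222A (2.13), ZSWIM6 (2.09), the interferon regulator IRF7 (3.11 ± 0.142 to 15.9 ± 2.29, 2.03, adjusted p = 4.52e-05), BAIAP2 (1.90), MAFA (1.77) and FGFR1 (1.70). DCXR was carried by a single library (221.4 ± 251.7 against 29.6 ± 2.59): its change of 2.24 became 1.33 without OTX015 replicate 2.

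Genes for ribosome assembly fell together, 28 of 35 lower and none higher (median -0.53, camera adjusted p = 3.76e-11, adjusted p = 0.00803 with an estimated correlation). NOP16 dropped from 51.4 ± 1.37 to 19.4 ± 1.70 (-1.37), RRS1 from 29.7 ± 0.143 to 12.7 ± 0.391 (-1.16) and the polymerase I subunit POLR1B from 27.3 ± 2.37 to 12.2 ± 0.740 (-1.10). Of the ribosomal proteins themselves none of 40 passed in limma, and none had an unadjusted p under 0.05 (RPL15 0.13, adjusted p = 0.312). Ribosomal protein genes rank high in every library, where the quantile step can hide a joint shift. B-lineage transcription factors fell (15 lower, 2 higher of 22, median -0.67, camera adjusted p = 3.05e-05, adjusted p = 0.0418 with an estimated correlation). POU2F2 (-1.56), SPI1 (-1.15) and TCF4 (-1.10) were in front. B-cell receptor signalling fell as well, 13 lower and 2 higher of 23 (14 and 2 adjusted over the list alone; median -0.47, camera adjusted p = 8.94e-05, adjusted p = 0.0602 with an estimated correlation). The linker BLNK went from 49.4 ± 1.84 to 15.6 ± 0.956 (-1.60), with CD72 (-1.41), BLK (-1.32) and PTPN6 (-1.16).

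Immediate early genes rose, 12 higher and 1 lower of 17 (15 and 2 adjusted over the list alone; median 0.75, camera adjusted p = 0.000308, adjusted p = 0.106 with an estimated correlation). JUN (1.25), IER3 (1.21) and EGR3 (1.15) led, all at low levels, and the call was lost among genes with a mean of at least 5 (median 0.63, adjusted p = 0.198). CDK inhibitors rose in 4 of 6 (median 0.64, camera adjusted p = 0.0181, adjusted p = 0.274 with an estimated correlation). CDKN2D (1.27), CDKN2C (0.80) and CDKN1B (0.58) were among them. G1/S regulators had 5 higher and 1 lower of 13 (6 and 2 adjusted over the list alone; camera adjusted p = 0.174, fry up 1.05e-05). CCNE2 (1.0), CDK2 (0.81) and E2F1 (0.75) were higher and CCND2 (-0.87) lower. In the P-TEFb and 7SK complex, MEPCE rose (0.78) and LARP7 fell (-0.79), 3 higher and 2 lower of 7 (camera adjusted p = 0.262, fry up 4.46e-07). Of the blood markers of BET inhibition, ZCCHC24 rose (1.73) and the list had 2 in each direction of 5 (adjusted p = 0.814).

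The other lists did not pass camera. NF-kB targets had 9 higher and 5 lower of 22 (9 and 6 adjusted over the list alone; adjusted p = 0.450). NFKBIA (21.2 ± 1.98 to 48.4 ± 3.54, 1.16) and CCL3 (1.10) were higher and LTA lower (-0.99). Interferon genes had 2 higher and 6 lower of 15 (adjusted p = 0.542), IRF7 up against OAS2 (-1.11) and MX2 (-1.07). The p53 targets had 6 higher and 1 lower of 15 (8 and 2 adjusted over the list alone; adjusted p = 0.174). SESN2 rose most (2.49 ± 0.0536 to 8.93 ± 0.951, 1.5) and AEN fell (-0.93). The ATF4 list had 6 higher and 4 lower of 17 (7 and 4 adjusted over the list alone; adjusted p = 0.395), with PPP1R15A (1.22) opposite TRIB3 (-1.0). Pro-apoptotic genes had 1 higher (PMAIP1, 0.60) and 3 lower (BMF, -0.63) of 10 (adjusted p = 0.516). Anti-apoptotic genes had 1 higher and 3 lower of 8 (2 and 3 adjusted over the list alone; CFLAR -0.77, adjusted p = 0.573). Mitotic genes had 6 higher and 4 lower of 30 (4 and 4 adjusted over the list alone; FOXM1 -0.53, UBE2C -0.52, adjusted p = 0.814). Recombination genes had 8 and 3 of 25 (CLSPN 0.81, RAD51D -1.42, adjusted p = 0.450). Heat shock genes had 2 higher (DNAJB1, 0.75) and 3 lower (HSPE1, -0.42) of 13, where median (-0.03) and mean (0.01) differ in sign (adjusted p = 0.814). Hypoxia genes had 4 higher (KDM3A, 0.75) and 1 lower (HK2, -0.61) of 17 (adjusted p = 0.516). Cholesterol genes had 5 higher (IDI1, 0.70) and 1 lower of 19 (adjusted p = 0.333). Nucleotide synthesis had 4 higher (MTHFD2, 0.50) and 7 lower (PFAS, -0.61) of 28 (4 and 9 adjusted over the list alone, adjusted p = 0.516). Histones, whose reads overlap between paralogs, had 2 higher of 20 (HIST1H2AC 2.17, H2AFJ 1.03, adjusted p = 0.301). Of cereblon ligase subunits none of 5 passed in limma, with 2 at an unadjusted p under 0.05 (CUL4B -0.24, CUL4A -0.19, adjusted p = 0.516 for the list). The VHL ligase had 1 higher of 5 (adjusted p = 0.814) and the proteasome 2 higher and 5 lower of 31 (1 and 3 adjusted over the list alone; PSMC1 -0.28, adjusted p = 0.611).

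OTX015 changed 3579 of the 9830 genes (1774 higher, 1805 lower; 36.4%), 416 of them at least 2-fold (147 higher, 269 lower). Libraries of both groups did not overlap at 6080 genes (61.9%), where chance gives 10%. The count was 5428 when only these groups were fitted.

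ARV-825 lowered MYC to 16.9 ± 1.31 from 235.6 ± 11.4 in control (n = 3 each; -3.73, SE 0.08, adjusted p = 5.38e-11). HEXIM1 rose to 28.2 ± 0.754 (2.0, adjusted p = 2.14e-08) and BRD2 to 252.8 ± 6.07 (1.15, SE 0.21, adjusted p = 0.000774), close to their levels under OTX015. MCL1 rose to 63.0 ± 1.96 (0.97, adjusted p = 3.14e-06), and BCL2L1 fell to 5.42 ± 1.02 (-1.31, adjusted p = 1.91e-05). CDKN1A rose to 46.4 ± 3.34 (0.92, adjusted p = 2.01e-05).

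IKZF1 fell to 49.2 ± 0.899 (-0.86), IKZF3 to 14.7 ± 1.55 (-1.06), PAX5 to 11.5 ± 1.0 (-0.61) and BTK to 86.2 ± 1.51 (-0.34), while IRF4 rose to 44.4 ± 0.644 (0.64). CCND1 (-0.16, adjusted p = 0.310), BCL2 (-0.27, adjusted p = 0.340) and VHL (0.11, adjusted p = 0.300) did not pass. CRBN, the ligase receptor that ARV-825 recruits, fell by 0.44 (adjusted p = 0.0164), a call lost without control replicate 2 or 3 (-0.42 each). CDK4 fell by 0.66 (adjusted p = 0.025), lost without ARV-825 replicates 1 (-0.67) or 3 (-0.61) or control replicates 1 (-0.60) or 3 (-0.67) or with no filter. BRD3 rose by 0.37 (adjusted p = 0.0277), lost without ARV-825 replicates 1 (0.39) or 3 (0.32) or control replicates 2 (0.33) or 3 (0.34) or when centred on ribosomal proteins (0.34). SERPINI1 stood at 1.14, untested.

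BZRAP1 showed the greatest rise, to 54.2 ± 5.66 (4.13), followed by KIAA1683 (0.808 ± 0.0685 to 13.7 ± 2.58, 3.0), the chemokine CCL4 (3.81 ± 0.589 to 34.8 ± 7.38, 2.88; reads shared with CCL4L2), the protease ASTL (2.55), ADAMTSL4 (2.47), ZSWIM6 (2.41) and IRF7 (19.6 ± 1.95, 2.32). The clone-named genes RP11-159D12.5 (2.36) and RP11-1035H13.3 (2.30) rose too, and can share reads with genes they overlap. After MYC, the deepest falls were LRRC14B (-3.59), SLA (-3.02), PLD6 (-2.71), IL16 (-2.47), TFAP4 (-2.36), the sulfotransferase CHST3 (7.59 ± 0.236 to 0.766 ± 0.150, -2.28), CD180 (-2.28), GAPT (-2.27) and the macrophage-type perforin MPEG1 (22.5 ± 1.5 to 3.99 ± 0.210, -2.24).

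Ribosome biogenesis fell again, 27 of 35 lower (28 adjusted over the list alone; median -0.50, camera adjusted p = 1.39e-08, adjusted p = 0.0190 with an estimated correlation). RRS1 fell to 7.93 ± 0.613 (-1.78), with NOP16 (-1.52) and POLR1B (-1.28). B-lineage factors had 14 lower and 2 higher of 22 (median -0.58, adjusted p = 0.00108, adjusted p = 0.0943 with an estimated correlation). POU2F2 (-1.57) and ID3 (-1.03) fell, and SOX11, a factor typical of mantle cell lymphoma, rose from 11.6 ± 2.11 to 23.1 ± 1.72 (0.95). B-cell receptor genes had 11 lower and 2 higher of 23 (12 and 2 adjusted over the list alone; median -0.34, adjusted p = 0.0112, adjusted p = 0.188 with an estimated correlation). CD79B went from 224.0 ± 15.3 to 81.0 ± 1.78 (-1.45). Immediate early genes rose in 14 of 17 with 1 lower (median 0.84, adjusted p = 5.03e-05, adjusted p = 0.0943 with an estimated correlation). EGR1 rose from 0.838 ± 0.146 to 7.33 ± 0.421 (2.18) and EGR3 by 2.17. The call was again lost among genes with a mean of at least 5 (0.84, adjusted p = 0.109). NF-kB targets rose, 12 higher and 4 lower of 22 (median 0.43, adjusted p = 0.0112, adjusted p = 0.160 with an estimated correlation). Members in front were CCL3 (2.16), NFKBIA (69.8 ± 4.48, 1.68) and TNF (1.61 ± 0.591 to 6.42 ± 0.725, 1.53). Cholesterol genes rose in 12 of 19 (13 adjusted over the list alone; median 0.42, adjusted p = 5.05e-05, adjusted p = 0.0943 with an estimated correlation). INSIG1 led (15.5 ± 0.933 to 44.0 ± 3.76, 1.44), before IDI1 (1.28) and HMGCS1 (0.79). CDK inhibitors rose in 4 of 6 (median 0.78, adjusted p = 0.0112, adjusted p = 0.188 with an estimated correlation). Histones were higher in 12 of 20 (median 1.26, adjusted p = 9.22e-05, adjusted p = 0.553 with an estimated correlation). Their reads are shared between paralogs (HIST1H2AC 2.92, HIST1H2BK 1.86).

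No other list passed under ARV-825 in camera. The p53 targets had 4 higher and 2 lower of 15 (SESN2 1.34, AEN -1.24) and the ATF4 list 6 and 4 of 17 (TRIB3 -1.56, XPOT -0.68). Interferon genes had 3 and 5 of 15 (3 and 6 adjusted over the list alone; STAT2 0.86, OAS2 -1.10) and recombination genes 6 and 3 of 25 (6 and 2 adjusted over the list alone; ATRIP 1.25, RAD51D -1.64). Pro-apoptotic genes had 1 higher and 4 lower of 10 (1 and 5 adjusted over the list alone): PMAIP1 rose from 29 ± 2.66 to 64.5 ± 4.03 (1.13), and BMF (-1.26) and BBC3 (-0.74) fell. Anti-apoptotic genes had 1 and 3 of 8, and G1/S regulators 5 and 2 of 13 (E2F3 0.74). Mitotic genes had 4 and 7 of 30 (3 and 6 adjusted over the list alone; FOXM1 -0.85), and heat shock genes 2 and 2 of 13 (DNAJB1 0.76). Hypoxia genes had 4 and 5 of 17 (ALDOC 1.04, MXI1 -0.78) and nucleotide synthesis 3 and 6 of 28 (MTHFD2 0.58, IMPDH2 0.58). The proteasome had 1 and 7 of 31 (PSMC1 -0.43), the cereblon ligase 1 and 1 of 5, and the VHL ligase 0 and 1 of 5 (none adjusted over the list alone). The P-TEFb list had 3 higher and 2 lower of 7 (LARP7 -0.88). The blood markers had 2 in each direction of 5, with a median of 1.28, a mean of -0.19 and fry down at 1.11e-06. Ribosomal proteins had none of 40 past the test in limma and none at an unadjusted p under 0.05, where again the quantile step can hide a joint shift.

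ARV-825 changed 4360 genes (1931 higher, 2429 lower; 44.4%), 693 at least 2-fold (242 higher, 451 lower), and 6483 genes (66.0%) did not overlap between the groups against 10% by chance.

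ARV-771 left MYC at 6.29 ± 0.461, against 235.6 ± 11.4 in control (n = 3 each; 32.5-fold on the shifted scale, -5.02, SE 0.08, adjusted p = 1.51e-12). In contrast to the other compounds, HEXIM1 fell, to 4.11 ± 0.357 (-0.51, adjusted p = 0.000138), and BRD2 fell to 57.7 ± 25.2 (-1.04, SE 0.21, adjusted p = 0.000886). MCL1, a short-lived survival factor, fell to 14.3 ± 1.44 (-1.09, adjusted p = 3.39e-07), and BCL2L1 to 9.12 ± 1.73 (-0.66, adjusted p = 0.00165). CCND1 fell to 201.6 ± 45.1 (-0.67, adjusted p = 0.000513) and CDKN1A to 13.1 ± 1.77 (-0.83, adjusted p = 1.95e-05). BRD3 (-0.20, adjusted p = 0.187) did not pass.

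IRF4 fell to 14.3 ± 2.28 (-0.94), IKZF3 to 11.8 ± 3.15 (-1.38) and IKZF1 to 63.4 ± 4.51 (-0.50), whereas PAX5 rose to 25.7 ± 0.629 (0.49, adjusted p = 0.000682). VHL, the receptor ARV-771 recruits, fell to 28 ± 3.23 (-0.41, adjusted p = 0.00116). CDK4 (-0.46, adjusted p = 0.0816), BCL2 (0.43, adjusted p = 0.109) and CRBN (0.15, adjusted p = 0.356) did not pass, and SERPINI1 stood at 0.259, untested. BTK fell by 0.22 (adjusted p = 0.0228). This call was lost without ARV-771 replicate 1 (-0.14) or control replicates 1 (-0.20) or 2 (-0.21), and after a correction for transcript length and GC (-0.05). It was lost too with only these groups fitted or when centred on ribosomal proteins (-0.26).

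ID3 led the falls under ARV-771 (50.9 ± 2.92 to 1.84 ± 0.760, -4.23, adjusted p = 2.34e-09), followed by the antiproliferative BTG1 (28.3 ± 3.11 to 0.649 ± 0.288, -4.16), RHOH (28.6 ± 2.5 to 1.03 ± 0.372, -3.88), SLA (-3.86), the amino acid transporter SLC38A2 (38.6 ± 2.97 to 2.41 ± 0.892, -3.57), TRIB1 (-3.55), C15orf39 (-3.50), the interferon regulator IRF1 (16.2 ± 0.685 to 0.713 ± 0.179, -3.33) and ZNF217 (-3.29). The genes that rose most were ASTL (0.188 ± 0.0856 to 14.9 ± 3.43, 3.72), the adrenergic receptor ADRA2B (0.0644 ± 0.0101 to 8.80 ± 1.08, 3.20), the nicotinic receptor subunit CHRNA10 (3.09), RASL11A (3.07), EGR3 (1.21 ± 0.236 to 16.6 ± 3.02, 2.98), the forkhead gene FOXI1 (0.0107 ± 0.0185 to 6.53 ± 0.0935, 2.90), BZRAP1 (2.87), ADAMTSL4 (2.56) and KIAA1683 (2.55), with RP11-159D12.5 (2.93) uncertain as before.

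Mitotic genes fell under ARV-771, 24 of 30 lower (25 adjusted over the list alone; median -0.71, camera adjusted p = 2.36e-06, adjusted p = 0.227 with an estimated correlation). Among them were AURKA (63.7 ± 3.07 to 14 ± 1.14, -2.11), CCNB1 (-1.53), TTK (-1.5) and KIF23 (-1.48). Heat shock genes fell in 11 of 13 (median -1.03, adjusted p = 8.26e-05, adjusted p = 0.227 with an estimated correlation). BAG3 fell to 1.45 ± 0.489 (-2.07) and HSPH1 to 72.0 ± 8.32 (-1.67), with HSPA1B (-2.28) and HSPA1A (-1.89), which share reads. The ATF4 list had 14 lower and 1 higher of 17 (median -0.82, adjusted p = 0.000888, adjusted p = 0.309 with an estimated correlation). DDIT4 fell furthest (11.1 ± 0.871 to 0.726 ± 0.443, -2.84), then TRIB3 (-2.39), DDIT3 (-2.17) and CEBPB (-2.00). Ribosome biogenesis had 22 lower and 1 higher of 35 (median -0.43, adjusted p = 0.000181, adjusted p = 0.174 with an estimated correlation). It was led by RRS1 (4.08 ± 0.753, -2.61), NOP16 (-2.21) and POLR1B (-1.98).

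The remaining lists did not pass camera, though many members moved. B-lineage factors had 13 lower and 5 higher of 22 (adjusted p = 0.0733; XBP1 48.5 ± 0.486 to 6.29 ± 0.312, -2.76; KLF2 -1.56). B-cell receptor genes had 10 lower and 3 higher of 23 (CD79B -1.78, BCL10 -1.76, VAV2 0.83). Interferon genes had 9 higher and none lower of 15 (9 and 1 adjusted over the list alone; median 0.62, adjusted p = 0.0733, fry up 5.4e-05), with IFI35 (1.47), ISG20 (1.12) and IFI6 (1.01). NF-kB targets had 8 higher and 6 lower of 22. CCR7, a homing receptor, fell from 25.9 ± 1.49 to 4.70 ± 0.952 (-2.25), while CCL4 (2.16), CCL22 (0.99) and EBI3 (0.95) rose. Immediate early genes had 6 higher and 8 lower of 17 (FOS 2.15, BTG2 -2.40). The p53 targets had 9 lower and 3 higher of 15 (adjusted p = 0.124, fry down 1.78e-06; AEN -1.85, SESN2 -1.48). G1/S regulators had 7 lower and 2 higher of 13 (adjusted p = 0.124, fry down 1.25e-08; CDC25A 12.3 ± 0.0652 to 1.10 ± 0.0475, -2.67; E2F2 -1.42; CCNE1 -1.35). The P-TEFb list had 4 lower of 7 (adjusted p = 0.105, fry down 1.68e-07; MEPCE 31.4 ± 0.588 to 7.43 ± 0.901, -1.95; HEXIM2 -1.44; CCNT1 -1.07). The blood markers had 3 lower of 5 (CD180 -2.94, adjusted p = 0.0733) and CDK inhibitors had 2 in each direction of 6 (CDKN2C -1.06, CDKN2A 0.93, CDKN1C 0.79).

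Pro-apoptotic genes had 7 lower and 2 higher of 10 (TNFRSF10A -1.49, BAK1 -1.20, BMF -1.16, BBC3 -1.08), and anti-apoptotic genes 3 lower of 8 (XIAP -0.55). Cholesterol genes had 11 lower and 3 higher of 19 (HSD17B7 -1.30; MVK -1.16; SQLE -0.95; adjusted p = 0.105). Hypoxia genes had 5 lower and 3 higher of 17 (4 and 3 adjusted over the list alone; SLC2A1 31.6 ± 0.460 to 5.73 ± 1.73, -2.31; EGLN3 -1.55; ALDOC 1.36), with a median of 0.03 against a mean of -0.16. Recombination genes had 8 lower and 5 higher of 25 (8 and 4 adjusted over the list alone; WEE1 -1.89, PALB2 -1.73, EXO1 -1.29, FANCA 0.82). Nucleotide synthesis had 6 lower and 3 higher of 28 (UMPS -1.05, APEX1 -0.74, RRM2 -0.56), with a median of 0.02 and a mean of -0.04. The proteasome had 9 lower and 2 higher of 31 (PSMB5 -0.93, PSMC6 -0.73). The cereblon ligase had 2 higher of 5 (1 adjusted over the list alone; RBX1 0.47) and the VHL ligase 2 in each direction of 5. Histones had 4 higher of 20 (3 adjusted over the list alone; HIST1H2AC 1.47, uncertain for shared reads). Among ribosomal proteins, RPL37 (0.24) and RPS4X (0.22) passed of 40, none adjusted over the list alone. The RPL37 call was lost without control replicate 2 (0.20) and the RPS4X call without control replicates 1 (0.23) or 2 (0.18), and both were lost when centred on the list itself or with only these groups fitted.

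Markers of other cell types were mostly silent and had no set test. Of 12 T-cell genes only LCK was tested, which B cells also express (-1.35 with OTX015, -1.03 with ARV-825, 0.05 with ARV-771, the last with adjusted p = 0.791). Of 12 myeloid genes only CD68 was tested: it rose under ARV-771 from 5.31 ± 0.925 to 19.9 ± 9.16 (1.66, adjusted p = 7.62e-05) and not under OTX015 (-0.04, adjusted p = 0.906) or ARV-825 (0.33, adjusted p = 0.284). Of the epithelial and stromal genes, VIM rose with OTX015 (0.37) and ARV-825 (0.34), and EPCAM rose with ARV-771 (1.72 ± 0.119 to 3.31 ± 0.495, 0.66).

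ARV-771 changed 1599 genes at least 2-fold, 446 higher and 1153 lower. Without the 2-fold limit 5954 passed (2851 higher, 3103 lower; 60.6%), or 4842 with only these groups fitted. Quantile normalization gives the libraries nearly the same distribution, so in every comparison higher and lower are relative to the other genes. A loss of mRNA across all genes would not show in these counts. In simulated data with the spread of each group, 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold among 9830. There 86 of 254 calls were false (33.9%), against 8 of 147 in a fit of these groups alone (5.44%) and 2 of 96 among calls of at least 2-fold. With so few genes changed, these shares cannot be carried over to the 5954 real calls. The pooled spread understates that of the ARV-771 libraries. At 5910 genes (60.1%) the groups did not overlap, against 10% by chance.

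**Figure D2:**
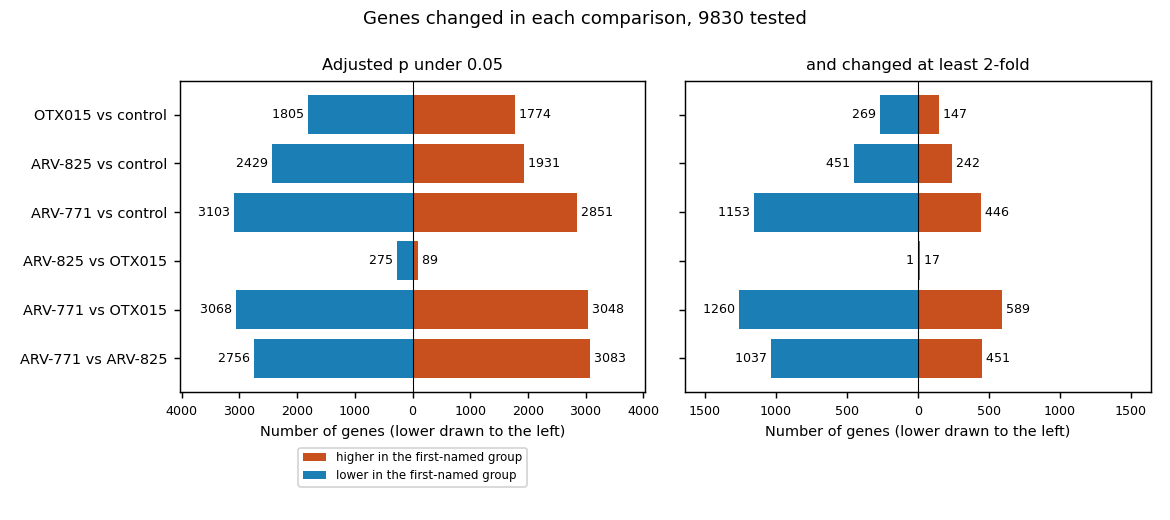
Genes lower (left) and higher (right) in each of the 6 comparisons, at an adjusted p under 0.05 and at least 2-fold. ARV-771 against control has 1153 lower and 446 higher at 2-fold or more, against 269 and 147 for OTX015.

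**Figure D3:**
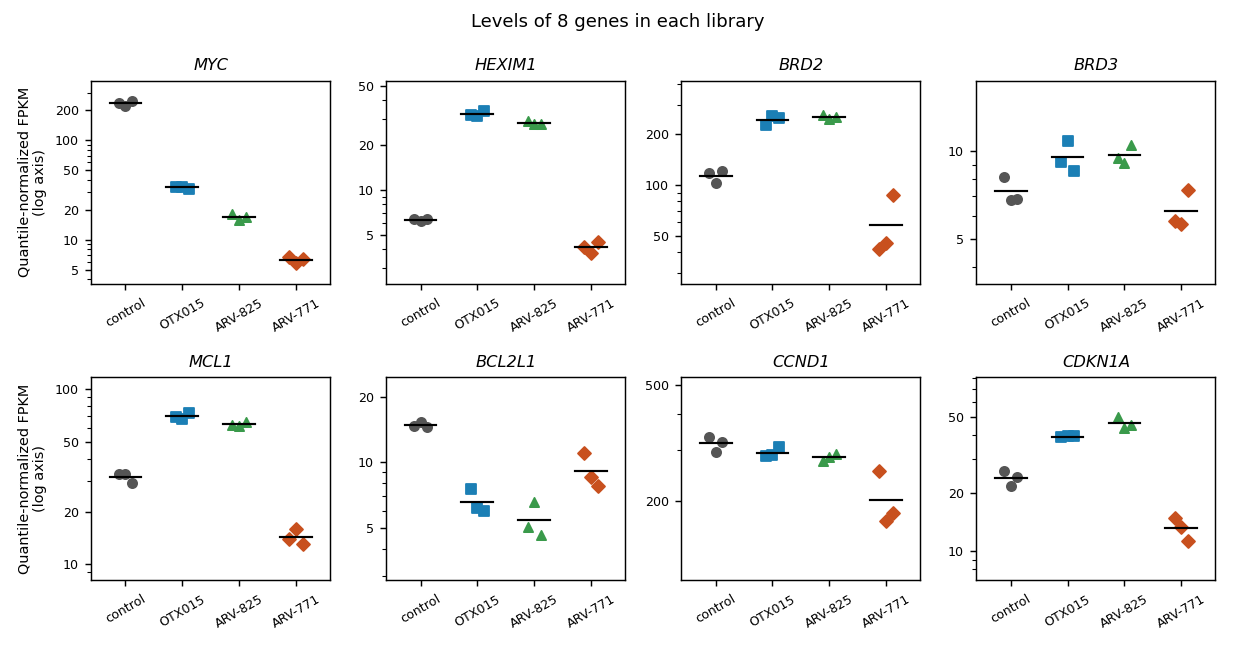
FPKM of MYC, HEXIM1, BRD2, BRD3, MCL1, BCL2L1, CCND1 and CDKN1A in each library on a log axis, with a line at the group mean. MYC falls from 235.6 to 33.5, 16.9 and 6.29, while HEXIM1, BRD2 and MCL1 rise under OTX015 and ARV-825 and fall under ARV-771.

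**Figure D4:**
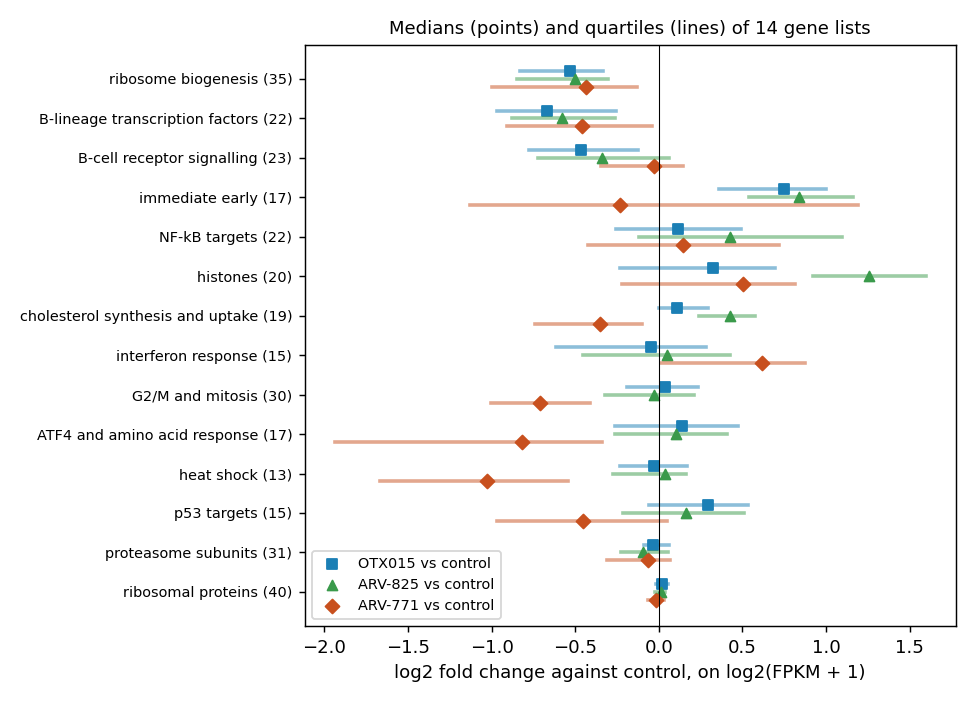
Log2 change against control for 14 gene lists, points marking medians and lines quartiles. Heat shock genes have a median of -1.03 under ARV-771, and ribosome biogenesis falls under all 3 compounds (-0.53, -0.50 and -0.43).

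At the same dose and time, ARV-825 left less MYC than OTX015, 16.9 ± 1.31 against 33.5 ± 0.776 (-0.95, SE 0.08, adjusted p = 0.000490). Among single genes TNF stood higher under the degrader, at 6.42 ± 0.725 against 2.25 ± 0.287 (1.19, adjusted p = 0.00357), as did CCL3 at 19.9 ± 3.27 against 8.90 ± 0.279 (1.06, adjusted p = 0.00747), EGR1 (1.11, adjusted p = 0.00332) and EGR3 (1.01, adjusted p = 0.00468). INSIG1, a sensor of sterol synthesis, was at 44.0 ± 3.76 against 22.3 ± 1.92 (0.95, adjusted p = 0.00217). Other leaders were NFE2L3 (27.1 ± 6.58 against 9.14 ± 1.61, 1.45), KIAA1683 (1.47), ASTL (1.41), ADAMTSL4 (1.39) and HIST1H2AK (1.64, reads shared between paralogs). Lower under ARV-825 were CCDC126 (2.83 ± 0.118 against 6.09 ± 0.824, -0.88) and DHRS13 (-0.82). SAP30 was lower (-0.89), a call lost without ARV-825 replicates 2 (-0.89) or 3 (-0.87) or OTX015 replicates 1 (-0.89) or 2 (-0.85). ZFP1 was lower (-0.96), a call lost without any one of the control, OTX015 or ARV-825 libraries (-1.04 to -0.89).

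For the target genes and most regulators no difference was called: BRD2 0.05 (interval -0.40 to 0.50), BRD3 0.03 (-0.24 to 0.29), HEXIM1 -0.19 (-0.36 to -0.02, adjusted p = 0.214), MCL1 -0.15 (-0.33 to 0.03), BCL2L1 -0.24 (-0.55 to 0.07), CDKN1A 0.23 (0.01 to 0.45, adjusted p = 0.247), CCND1 -0.05 (-0.32 to 0.21), PAX5 0.29 (0.09 to 0.49, adjusted p = 0.107) and CRBN -0.09 (-0.38 to 0.20). The remaining genes of that set were IRF4 0.23, IKZF1 -0.06, IKZF3 0.28, BTK 0.12, BCL2 0.13, CDK4 -0.12 and VHL -0.16, none called. A p that misses the threshold does not show that the compounds act alike on these genes.

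Cholesterol genes stood above OTX015 in 7 of 19 (11 adjusted over the list alone; median 0.35, camera adjusted p = 9.43e-12, adjusted p = 0.0151 with an estimated correlation). IDI1 was at 65.4 ± 2.03 against 43.4 ± 1.76 (0.58, adjusted p = 0.0110; lost without ARV-825 replicate 2 (0.57) or OTX015 replicate 2 (0.55)). NF-kB targets were higher in 7 of 22 (9 adjusted over the list alone; median 0.25, adjusted p = 2.63e-07, adjusted p = 0.0151 with an estimated correlation). Histones passed camera with 1 higher of 20 (2 adjusted over the list alone; median 1.03, adjusted p = 1.04e-09, adjusted p = 0.364 with an estimated correlation). B-cell receptor genes passed (median 0.13, adjusted p = 0.00663, adjusted p = 0.181 with an estimated correlation) with no member called by limma over all genes, 2 higher and 1 lower adjusted over the list alone, and 5 higher and 1 lower at an unadjusted p under 0.05. Immediate early genes (2 higher and 1 lower of 17, 3 and 1 adjusted over the list alone; median 0.11, adjusted p = 0.0404, adjusted p = 0.364 with an estimated correlation) lost the call without ARV-771 replicate 1 (0.11), ARV-825 replicates 1 (0.09) or 2 (0.13) or OTX015 replicate 3 (0.11). Interferon genes passed too (median 0.13, adjusted p = 0.0162, adjusted p = 0.181 with an estimated correlation). None of the 15 was called by limma over all genes or over the list alone, and 1 was higher at an unadjusted p under 0.05. The interferon call was lost without ARV-825 replicate 2 (0.12) or OTX015 replicate 3 (0.14). Without a filter on low values neither immediate early nor interferon genes were called (0.05 and 0.02).

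In total 364 genes differed between ARV-825 and OTX015 (89 higher, 275 lower; 3.70%), with 1839 at an unadjusted p under 0.05 and 18 at least 2-fold (17 higher, 1 lower; 24 and 35 with a pseudocount of 0.1). The excess of lower genes was not kept without ARV-825 replicate 3 (29 higher, 26 lower), and was small without OTX015 replicates 1 (28 and 34) or 2 (24 and 26). The total depends in part on libraries outside the comparison, which enter only through the spread estimate. It was 1645 with only these groups fitted, and 964, 378 and 1119 without ARV-771 replicates 1, 2 and 3. It was 121, 73 and 55 without ARV-825 replicates 1, 2 and 3, 187, 176 and 190 without each control in turn, and 62, 50 and 118 without each OTX015 replicate. At 3523 genes (35.8%) the libraries did not overlap, against 10% by chance.

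ARV-771 lay far below OTX015 at several genes that OTX015 had raised. HEXIM1 was at 4.11 ± 0.357 against 32.3 ± 1.15 (-2.70, adjusted p = 3e-10), MCL1 at 14.3 ± 1.44 against 70.1 ± 2.51 (-2.22, adjusted p = 1.36e-09) and BRD2 at 57.7 ± 25.2 against 244.8 ± 16.8 (-2.14, SE 0.21, adjusted p = 2.39e-06). MYC was lower as well (-2.24, adjusted p = 1.01e-09). CDKN1A (-1.53), IRF4 (-1.35), VHL (-0.68), CCND1 (-0.56) and BRD3 (-0.54) were also lower, while PAX5 (1.38), BCL2 (0.84), CRBN (0.50) and IKZF1 (0.30) were higher. BCL2L1 was higher by 0.41, lost without ARV-771 replicate 1 (0.28) or OTX015 replicates 2 (0.38) or 3 (0.36) and with only these groups fitted. BTK was higher by 0.25, lost with only these groups fitted or when centred on ribosomal proteins. CDK4 (0.08, interval -0.38 to 0.54) and IKZF3 (-0.05, interval -0.39 to 0.29) were not called. The greatest falls were SLC38A2 (2.41 ± 0.892 against 53.1 ± 5.91, -4.02), BTG1 (-3.86), B3GNT2 (0.455 ± 0.241 against 18.1 ± 0.741, -3.73), TIPARP (0.290 ± 0.0671 against 16.0 ± 0.613, -3.72) and C15orf39 (-3.63), and the greatest rises ADRA2B (2.92), FOXI1 (2.86), ASTL (2.57), CHRNA10 (2.52) and RASL11A (2.40).

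Mitotic genes were lower in 24 of 30 and higher in 1 than under OTX015 (AURKA -1.88, KIF23 -1.66; camera adjusted p = 8.91e-06, adjusted p = 0.176 with an estimated correlation). Lower too were the ATF4 list in 13 of 17 (1 higher; DDIT3 -2.64, DDIT4 -2.55; 0.000615, adjusted p = 0.312 with an estimated correlation) and heat shock genes in 9 of 13 (1 higher; BAG3 -2.59, HSPH1 -1.67; 0.000615, adjusted p = 0.182 with an estimated correlation). G1/S regulators (8 of 13, 1 higher; CDC25A -2.78, CCNE1 -2.03; 0.0279, adjusted p = 0.176 with an estimated correlation) and p53 targets (10 of 15, 1 higher; SESN2 -2.98; 0.0272, adjusted p = 0.176 with an estimated correlation) were also lower, as were the blood markers (4 of 5; ZCCHC24 -1.61; 0.0146, adjusted p = 0.176 with an estimated correlation). B-cell receptor genes stood higher, 16 of 23 against 4 lower (CD72 19.6 ± 1.86 against 5.85 ± 1.16, 1.6; BLK 1.29; median 0.37, 0.0272, adjusted p = 0.182 with an estimated correlation). Interferon genes were higher in 11 of 15 and lower in 3 (MX1 10.8 ± 0.793 against 3.43 ± 0.167, 1.41; 0.0395, adjusted p = 0.182 with an estimated correlation), a call lost without ARV-771 replicate 1 (0.52). The P-TEFb list (5 of 7 lower, 1 higher; MEPCE -2.73, CCNT1 -1.39; 0.0417, adjusted p = 0.182 with an estimated correlation) lost its call without ARV-771 replicate 2 (-0.98). Cholesterol genes (11 of 19 lower, 1 higher; MVK -1.41; 0.0360, adjusted p = 0.312 with an estimated correlation) lost theirs without ARV-771 replicate 3 (-0.47). Median and mean differ in sign for B-lineage factors (0.28 and -0.02; neither camera, 0.475, nor fry, 0.128, passed) and anti-apoptotic genes (0.15 and -0.09; camera 0.997, fry down at 0.000148). With weights per library the calls were lost for G1/S regulators (-0.77), p53 targets (-0.65), blood markers (-1.68), cholesterol (-0.29), interferon (0.56) and P-TEFb genes (-1.10). All of these but the first were also lost among genes with a mean of at least 5. At least 2-fold differences numbered 1849 (589 higher, 1260 lower) of 6116 called, or 5075 called with only these groups fitted. In simulated data with as few genes changed as before, 71 of 244 calls of this comparison were false (29.1%), 16 of 154 in a fit of these groups alone (10.4%) and 4 of 93 among those of at least 2-fold. These shares cannot be carried over to the real calls.

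Between the degraders, ARV-771 gave the lower MYC (6.29 ± 0.461 against 16.9 ± 1.31, -1.29, adjusted p = 6.71e-08). HEXIM1 (-2.51), BRD2 (-2.19, SE 0.21, adjusted p = 2.52e-06), MCL1 (-2.07), CDKN1A (-1.75), IRF4 (-1.58), BRD3 (-0.57), VHL (-0.52) and CCND1 (-0.50) were lower as well. PAX5 (1.09), BCL2L1 (0.66), CRBN (0.59) and IKZF1 (0.36) were higher, and BCL2 (0.71) was too, except without ARV-825 replicate 3 (0.59, not called) or with only these groups fitted. IKZF3 (-0.33, interval -0.67 to 0.01), CDK4 (0.20) and BTK (0.12) were not called. SESN2, a stress-induced inhibitor of growth signalling, was at 0.263 ± 0.154 against 7.86 ± 0.928 (-2.81). TIPARP (-3.70), SLC38A2 (-3.67), BTG1 (-3.66), ZNF217 (-3.49) and B3GNT2 (-3.40) differed most downwards and FOXI1 (2.88), RASL11A (2.33), ADRA2B (2.28), IQSEC1 (10.8 ± 0.930 against 1.61 ± 0.254, 2.18) and HOXA10 (1.99) upwards.

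Cholesterol genes were lower under ARV-771 in 14 of 19 and higher in 1 (INSIG1 9.93 ± 1.38 against 44.0 ± 3.76, -2.04; IDI1 -1.77; median -0.84, camera adjusted p = 9.59e-05, adjusted p = 0.137 with an estimated correlation). Immediate early genes (11 of 17, 3 higher; BTG2 -2.56, JUND -2.17; 0.00658, adjusted p = 0.149 with an estimated correlation) and the ATF4 list (13 of 17, 1 higher; CEBPB -2.36; 5.84e-05, adjusted p = 0.224 with an estimated correlation) were lower as well. This held also for heat shock genes (9 of 13, 11 adjusted over the list alone, 1 higher; BAG3 -2.61; 6.07e-05, adjusted p = 0.139 with an estimated correlation) and mitotic genes (24 of 30, 1 higher; CDK1 -1.5; 4.91e-06, adjusted p = 0.137 with an estimated correlation). So it did for G1/S regulators (7 of 13; CCNE1 -2.13; 0.0161, adjusted p = 0.137 with an estimated correlation), blood markers (4 of 5; 0.00407, adjusted p = 0.137 with an estimated correlation) and p53 targets (9 of 15, 2 higher; 0.0331, adjusted p = 0.149 with an estimated correlation), the last lost without ARV-771 replicate 3 (-0.35). With weights per library G1/S regulators (-0.55) and p53 targets (-0.29) were not called, the latter also not among genes with a mean of at least 5 (-0.51). NF-kB targets did not pass as a set (12 lower and 7 higher of 22, 13 and 7 adjusted over the list alone, 0.109), though TNF was at 0.355 ± 0.138 against 6.42 ± 0.725 (-2.45) and CCL3 was lower (-2.31). At least 2-fold differences numbered 1488 (451 higher, 1037 lower) of 5839 called, or 4650 with only these groups fitted. In simulated data with as few genes changed as before, 87 of 265 calls were false (32.8%), 19 of 159 in a fit of these groups alone (11.9%) and 6 of 106 among those of at least 2-fold. Here too the shares cannot be carried over to the real calls.

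Responses to OTX015 and ARV-825 ran closely together across genes (r = 0.889), those to OTX015 and ARV-771 little (0.229), and those to ARV-825 and ARV-771 in between (0.406). Sharing the controls alone gave r = 0.502 on average in simulated data with one spread per gene (at most 0.629, covariance 0.0160). With the spread of each group it gave 0.534, 0.311 and 0.321 for these pairs (at most 0.807, 0.585 and 0.602). Neither r with ARV-771 exceeds the highest of these draws. As no gene changed in the draws, their r is made of noise alone. It is therefore no bound for the r of real responses, and the covariance is the measure to compare. The covariances were 0.229, 0.0825 and 0.170, above the highest simulated with the spread of each group (0.0304, 0.0293 and 0.0302). OTX015 and ARV-825 shared 1402 higher and 1596 lower genes, against 348.5 and 446.0 for independent lists, with 2 genes opposite against 792.9. OTX015 and ARV-771 shared 699 higher and 865 lower (514.5 and 569.8 for independent lists), and 847 genes such as HEXIM1, MCL1 and BRD2 went opposite ways, fewer than the 1083.5 of independent lists. ARV-825 and ARV-771 shared 944 and 1363 (560.0 and 766.8), with 665 opposite against 1314.0. With 3 controls, which cannot be divided into sets of at least 2 each, part of the excess over independent lists may come from the controls in common.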

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

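The tests without the ARV-771 libraries, with a correction for transcript length and GC, and with simulated controls at the spread of each group were chosen after the data had been seen; the others were planned. Each result was recomputed under the settings that kept its genes and groups. The simulated controls were used only for the agreement between responses. Of 282 recomputed counts of changed genes, 249 stayed within 1.5 times the reported count, 19 fell below and 14 rose above. These totals take no account of direction. Centred on the median of all genes, ARV-771 against control had 3077 higher and 2950 lower, where the reported fit had 2851 and 3103. For named genes 16268 of 16965 values kept direction and side of the threshold, 417 lost their call, 278 gained one and 2 reversed. For gene lists the numbers were 3582 of 3666, with 33 calls lost, 51 gained and none reversed, and all 70 values of agreement between responses held. With no gene changed, the r simulated for shared controls was 0.502 at one spread per gene. When each group was given its own spread it fell to 0.311 (OTX015 and ARV-771) and 0.321 (ARV-825 and ARV-771), and was 0.534 for OTX015 and ARV-825. The reversals were IKZF3 (0.15 with library weights) and RPS15 (-0.24 corrected for length and GC), both in ARV-771 against OTX015 and neither called there in the reported fit. The cause was not tested.

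With the pseudocount at 0.1, 697 genes changed at least 2-fold under OTX015, 1077 under ARV-825 and 59 between ARV-825 and OTX015 (24 higher and 35 lower, where the reported fit had 17 and 1), since a smaller constant widens folds of low genes, while 225 genes differed between those compounds in all. Among genes with a mean of at least 5, where fewer genes are tested, the 2-fold counts were 262, 399 and 969 for OTX015, ARV-825 and ARV-771 against control, 9, 1133 and 920 between compounds, and 117 genes differed between ARV-825 and OTX015. A fit without the widely spread ARV-771 libraries gave more: 5428 genes for OTX015 against control with only these groups and 5474 without the 3 ARV-771 libraries, and for ARV-825 against OTX015 1645 (29 at least 2-fold) and 1851. Library weights gave 5744 and 2353 (49 at least 2-fold), resting on a weight of 52.5 for ARV-771 replicate 2 against 0.104 and 0.0705 for the others. ARV-825 against OTX015 also gave 241 when centred on ribosomal proteins, 776 corrected for length and GC, and 226 with a replicate block. The replicate block gave 3636, 4370 and 5985 for the comparisons with control, and same-numbered replicates were no closer than others: their own number was the best match in 4 of 18. For these shifts, unless a reason is given, the cause was not tested. Leaving out each library in turn gave 2744 to 4741, 3504 to 5431 and 5283 to 6682 changed genes against control. Between compounds it gave 50 to 1119 (ARV-825 against OTX015), 5492 to 6874 and 5065 to 6692. Read depth is not known, so what it limits was not analysed here.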

Other observations

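The tests on replicate 3, on myeloid RNA, on exon number, and on GC-matched and downstream neighbours were chosen after the results were seen, as were the gene families and the genes named in this part outside the naming rule. A set of 391 genes rose under both OTX015 and ARV-825 and fell under ARV-771. TIPARP, a mono-ADP-ribosyltransferase, changed by 1.36, 1.34 and -2.36 in that order, the p53 phosphatase PPM1D by 0.76, 0.77 and -2.02, CCNG2 by 0.40, 0.42 and -2.62, PNRC1 by 1.0, 0.92 and -2.16, and the costimulatory ligand TNFSF9 by 0.79, 0.91 and -2.05. The opposite course was taken by 165 genes, such as the B-cell regulator IRF8 (-0.71, -0.62 and 0.66), the antiviral MX1 (-0.74, -0.48 and 0.68) and IQSEC1 (-1.75, -1.54 and 0.63). In all 3 comparisons 622 genes rose, among them the linker histone gene H1FX (1.66, 1.73 and 2.07) and VAMP1 (1.1, 1.29 and 1.27). In all 3, 845 fell, among them IKZF2 (-2.21, -2.16 and -2.45), TLR10 (-2.08, -2.17 and -2.45), HMOX1 (-2.05, -2.04 and -1.45) and SASH3 (-1.84, -1.99 and -1.96). No count expected for independent lists was computed for these sets. By pairs, opposite calls were fewer than for independent lists (847 against 1083.5 for OTX015 and ARV-771, 665 against 1314.0 for ARV-825 and ARV-771). The 391 and 165 genes therefore do not show an excess of opposite responses. The controls are common to these comparisons, and their part in the overlap was not separated.

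Gene families were counted without a set test. The signs of their medians under ARV-771 were kept when centred on ribosomal proteins or on the median of all genes. After the quantile step these references already lay close together across libraries (10.7 to 10.9 and 3.62 to 3.66 in log2). Centring could therefore move the values little, and it cannot show a global loss of mRNA. Of 323 zinc finger genes 184 were lower and 31 higher under ARV-771 (median -0.60), 104 lower and 60 higher under ARV-825 (-0.11) and 43 lower and 65 higher under OTX015 (0.06). Subunits of RNA polymerases I and III were lower in 9, 10 and 10 of 13 under OTX015, ARV-825 and ARV-771 (1 higher under ARV-771; medians -0.44, -0.46 and -0.56). Of 12 polymerase II subunits 2 were higher and 10 did not pass under OTX015 and under ARV-825 (medians 0.02 and -0.04), with POLR2A at 1.67 and 1.79. The OTX015 median turned to -0.005 when centred on ribosomal proteins. Under ARV-771 2 of these subunits were higher and 1 lower (median 0.10). MHC class II genes were higher in 7 of 13 and lower in 1 under ARV-771 (median 0.38). Mitochondrially encoded genes were higher in 7 of 12 and lower in none under ARV-771 (median 0.80). Their share of the summed values was 23.5% in replicate 3 and 9.77% and 11% in the others, against 8.29% to 12.4% in control. Only replicate 3 lay outside the control range of this share. MT-CO3 (-4.85, adjusted p = 0.124) and MT-ATP6 (-4.06, adjusted p = 0.1695) were listed at 0 in that library. Genes with few exons fell most often under ARV-771: at least 2-fold in 36.0% of 222 single-exon genes, 31.3% of 904 with 2 to 3 exons, 14.6% of 3374 with 4 to 8 and 5.60% of 5321 with 9 or more. After the correction for transcript length and GC the shares were 35.6%, 31.7%, 13.8% and 5.11%. The uncorrected shares were 8.56%, 8.74%, 5.36% and 3.23% under ARV-825 and 3.15%, 4.76%, 2.87% and 2.29% under OTX015.

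ARV-771 changed 1599 genes at least 2-fold, far more than the other compounds. Neither a bias of transcript length or GC nor replicate 3 alone accounts for it, as 1509 genes passed after removing each library's trend (1338 in common) and 1750 without that replicate (1447 in common). Myeloid markers were mixed and do not decide whether RNA of myeloid cells was present. MPO was listed at 0 in control and averaged 3.72 in ARV-771. CD68 (5.31 to 19.9), ITGAM (0.194 to 2.61), LYZ (0.403 to 1.05) and CD14 (0.0131 to 0.750) were higher as well. The most abundant of S100A8, S100A9, ELANE and FCN1, picked after the values were seen, reached 0.0875. Of the 12 listed markers 4 had a mean of at least 1 against 1 in control. Decay of short-lived mRNA after loss of transcription was the biological candidate. Genes with an AU-rich motif in the 3' UTR differed from the rest by -0.0634 after the correction for length and GC (bootstrap -0.0945 to -0.0248, permutation p = 3e-04, 9566 genes searched). This fell short of the -0.1 set for corrected values before the test was run. The presence of such a motif itself depends on length and GC, so the correction may remove part of the signal. Uncorrected the difference was -0.172, and 45.7% of genes at least 2-fold lower carried the motif against 38.3% of all. Decay was thus neither shown nor excluded as a cause. For the 1599 genes as a whole, no other biological cause particular to ARV-771 was tested.

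For genes raised by ARV-771 a candidate explanation is transcription that runs on from an expressed gene upstream. Of 442 coding genes at least 2-fold higher, at any level in control, 110 (24.9%) had an expressed gene on the same strand ending within 10 kb upstream, against 10.6% of unchanged genes matched on level, a ratio of 2.35 (permutation p = 1e-04, the smallest they can give). Matched on GC as well the ratio was 1.70, and for downstream neighbours it was 0.874. The ratio was 1.39 for ARV-825 (permutation p = 0.0191) and 1.02 for OTX015 (permutation p = 0.5). Gene-level FPKM cannot show reads between genes, so run-on transcription stays a hypothesis.

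The difference between ARV-825 and OTX015 may hold a component that ARV-771 shares. Across genes it correlated with ARV-771 minus control, which has no library in common with it, at r = 0.455. Of all 364 genes called in the difference 325 had the sign of ARV-771, and of the 322 called in both 299 (92.9%) did. Of the 275 genes lower under ARV-825 240 were also called lower under ARV-771, and of the 89 higher ones 59 were also called higher. The lists that camera called higher than under OTX015 were divided. Medians under ARV-771 against control had the same sign for NF-kB targets (0.14), histones (0.50) and interferon genes (0.62). They had the other sign for cholesterol (-0.35), immediate early (-0.23) and B-cell receptor genes (-0.03). The r of 0.455 was not recomputed after the correction for length and GC. Whether ARV-825 gave the same response as OTX015 at a greater size could not be told, at r = 0.117 with 0.0776 to 0.144 over the OTX015 libraries. This r set 1 OTX015 library against the other 2, so noise lowers it and it cannot be ranked against 0.455. Of the 364 genes 242 had the sign of the OTX015 response, which has libraries in common with the difference. Off-target effects of either degrader were not tested.

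With 3 libraries against 3, the 10 splits of the libraries are too few to give a share under 0.05. In each case 1 split, the real one, gave as many genes, and the highest other count was 0. Every other split put libraries of both groups on each side, so any difference between the groups widened the spread estimate. That presses the other counts towards 0, and they are no separate evidence for the real ones. The real counts were 3579 for OTX015, 4360 for ARV-825 and 5954 for ARV-771 against control, and 416, 693 and 1599 at least 2-fold. Between compounds they were 364 for ARV-825 against OTX015, 6116 for ARV-771 against OTX015 and 5839 for ARV-771 against ARV-825, and 18, 1849 and 1488 at least 2-fold.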
